A study of Drosophila palustris with 2 samples.

How the data were processed

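RNA was extracted with Trizol from whole bodies of mixed male and female adults, and libraries were prepared from 1 µg of RNA after poly(A) selection with a directional kit, per the labels' protocols. Reads were handled with fastp and STAR 2.7.11b, per the submitters' processing notes; the version of fastp and the settings were not given in the sources used here. The genes were predicted with BRAKER 3.0.6 using these reads as evidence, per the series' design text. Each deposited table holds raw counts of reads per gene for 1 library, in the layout of STAR's gene counting, with 3 columns that count the same reads without strand, on the forward strand and on the reverse strand. Whether a counted unit is a read or a read pair was not given in the sources used here, and "read" is used for both. The tables give locus tags without gene names or coordinates, no genome or name table was used here, and so gene lists fixed before the data were examined (yolk and eggshell, germline, muscle, photoreceptor, digestive, fat body, immune, heat shock and ribosomal genes) were not analysed here.

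The reverse-strand column was taken as the sense count, as the directional kit implies, and checked: it held 46610675 and 39026623 reads against 373551 and 380585 in the forward-strand column, which was taken as antisense. The 4 leading entries of each table name no gene (unmapped, multimapping, no feature, ambiguous) and were kept out of library sizes and tests; with sense counting they made up 26.8% of replicate 1 and 30.1% of replicate 2. The sum of the stranded counts minus the unstranded count of a gene was read as the reads it shared with an annotated feature on the other strand; a read shared by 2 genes counts in both.

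Both libraries form 1 group and their replicate numbers come from the sample titles. No comparison between groups is implied, so no quasi-likelihood test between groups was run. Counts were scaled by TMM (edgeR 4.0.16 in R 4.3.3; factors 1.02 and 0.981) and given as CPM of sense reads. A gene was taken as detected at 10 or more sense reads in each library. Agreement was measured by the correlation of log2(CPM + 1), by a chi-square test of the 2 columns and by the common dispersion of an intercept-only edgeR fit, which has 1 residual degree of freedom per gene. Differences between the 2 libraries were tested with a two-sided exact binomial test per gene given its total, over genes with 10 or more sense reads in each library or 20 or more in total, with Benjamini-Hochberg adjustment, and called at an adjusted p of under 0.05 and at least 2-fold, with 0.5 added to each count for the ratio. The p-values measure counting error between these 2 libraries and have no replicate check. Intervals on shares are 95% Wilson intervals and intervals on ratios of single genes are exact (Clopper-Pearson). A count of 0 allows up to 3 reads. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

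Named genes followed a rule set before the data were examined: the 5 tags with the highest mean CPM, the 2 with the largest ratio in each direction among called genes with at least 100 reads in total, and the 2 with the most reads among those with more antisense than sense reads. Tags named outside this rule are marked as chosen after their values were seen. The alternatives tried were unstranded counts, other read minimums, no filter, DESeq2 1.42.0 size factors and total reads in place of TMM, other pseudocounts and fold minimums, leaving out the 100 highest genes, the DESeq2 dispersion fit, and each library alone.

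The test of differences was tested on simulated data drawn from the real means and library sizes, with 200 changed genes. With a spread of 20% between pools, it called 47.8% of 67 genes changed 2-fold, 98.5% of 67 changed 4-fold and 100% of 66 changed 8-fold, over 13686 genes tested for replicate 2 against replicate 1. Genes changed 2-fold lie at the cutoff itself, and their share was only 52.2% even with counting noise alone. With the 20% spread the test also called 368 of 13486 unchanged genes, against 0 of 13481 with counting noise alone. A call thus shows a difference between the libraries beyond counting noise and no more. The estimated coefficient of variation was 19.9% over the unchanged genes and 23.2% when the changed genes were included.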

Results

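Polyadenylated RNA was sequenced from whole adults of Drosophila palustris, a fruit fly of the quinaria group of the subgenus Drosophila. The series was made to support the annotation of a draft genome, in which the RNA reads served as evidence for gene prediction. It held 2 libraries of 1 group, each from a separate pool of 10 to 20 adults of both sexes, and no treatment, sex or tissue was contrasted. The questions the data can answer are therefore how much of the annotation was transcribed in adults, on which strand, at what levels, and how closely the 2 pools agreed. Replicate 1 held 63649388 reads and replicate 2 held 55800005. Genes carried locus tags alone, without names, so they are identified here by tag and no function or genomic position is given.

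Most of the reads fell on annotated gene features, and 20.6% to 22.7% fell on none. On average 71.6% ± 2.33 of all reads (SD, n = 2) were assigned to a gene on the sense strand. That share was 73.2% in replicate 1 (95% Wilson interval 73.2 to 73.2) and 69.9% in replicate 2 (69.9 to 70.0). Reads assigned to no annotated feature made up 20.6% of replicate 1 and 22.7% of replicate 2. STAR counts overlap with annotated exons, so this share includes any reads from introns as well as reads outside the gene models. The latter include any part of a transcript that its model leaves out, and these sources were not separated. Multimapping reads, which were left out of the gene counts, made up 3.42% and 4.61%. Unmapped reads came to 2.33% and 2.48%, and reads shared by overlapping genes to 0.374% and 0.306%. The 2 libraries differed in each of these shares by more than their counting intervals, and with 2 libraries the difference between pools had no further replicate check. Ignoring strand gave a gene or an ambiguous overlap to only 2.46% of the no-feature reads in replicate 1 and 2.61% in replicate 2, so few of them lay on annotated exons of the other strand.

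Of 20053 annotated gene models, 13454 (67.1%) had at least 10 sense reads in each library. At least 1 sense read was found in each library for 15195 models (75.8%). No sense read was found in either library for 3452 models (17.2%), against 861 expected if the zeros of the 2 libraries were independent of each other. Libraries of the same kind of sample share their unread genes, so this excess was fixed in advance and nothing is concluded from it. Of the 3452, 2730 had no read on either strand, which at these depths allows up to 3 reads per library. That bound covers reads assigned to a single gene only, since multimapping and ambiguous reads are not in the gene counts. The 1406 models read in one library alone had a median of 1 read and at most 39. Thinning the deeper library to 50% of its reads lost between 3.23% and 3.60% of the 15899 models with a sense read there, over 20 draws. Because the reads had been used to predict the genes, detection was not independent of the annotation.

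Detected models were mostly expressed at moderate levels, given here as CPM (counts per 1000000 sense reads, scaled by TMM). CPM is not corrected for transcript length, so levels and ranks of different genes compare reads and not numbers of transcripts. Over the 13454 models the median was 24.1 CPM, 25% of models lay under 6.71 CPM, 75% under 56.9 CPM and 95% under 225 CPM. The largest expressed class, 7491 models (37.4% of the annotation), had a mean of 10 to 100 CPM and took 28.9% of the sense reads in replicate 1 and 28.5% in replicate 2. The 1632 models of 100 to 1000 CPM took 37.4% and 38.3%. Only 154 models (0.768%) exceeded 1000 CPM, and these took 32.2% and 31.7%. At the other end, 3205 models of 1 to 10 CPM held 1.43% and 1.47% of the sense reads, and 4119 models above 0 and up to 1 CPM held 0.0828% and 0.0831%.

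**Figure D1:**
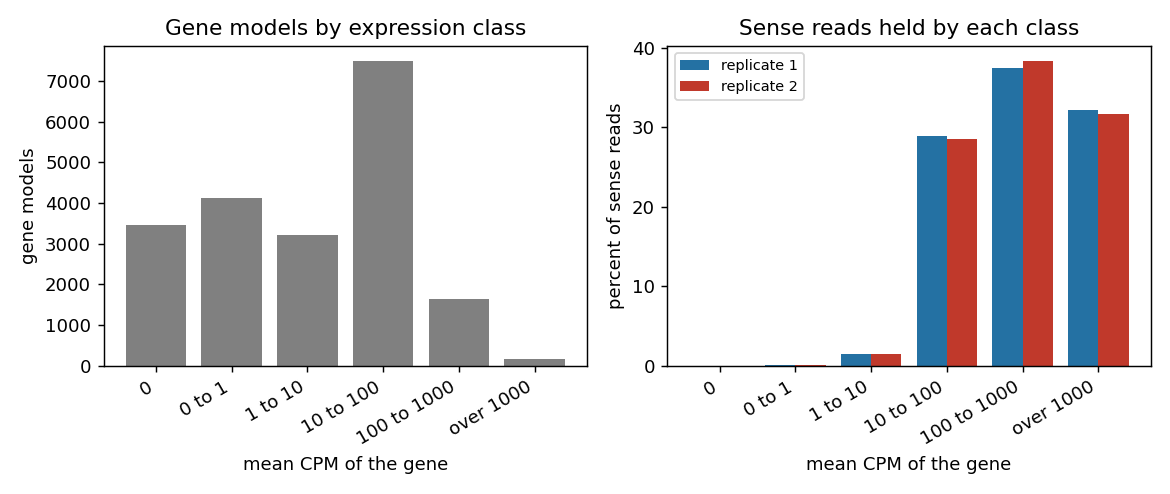
Gene models by mean expression over the 2 libraries (left, bars are numbers of models per class of mean CPM) and the percent of each library's sense reads that each class held (right, 1 bar per library). The 154 models over 1000 CPM held 32.2% of the sense reads in replicate 1 and 31.7% in replicate 2, and the 4119 models of 0 to 1 CPM held under 0.1% in each.

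The reads were concentrated in a small part of the gene set. Only 523 models in replicate 1 and 514 in replicate 2 held 50% of the sense reads, which is 2.61% and 2.56% of the annotation. The 100 highest models held 25.4% ± 0.298 of the sense reads (SD, n = 2), with 25.6% in replicate 1 (95% Wilson interval 25.6 to 25.6) and 25.2% in replicate 2 (25.2 to 25.2). The 1000 highest held 59.9% ± 0.292. No single gene dominated either library: the 5 highest together took 4.25% of replicate 1 and 3.58% of replicate 2.

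The highest gene by mean was ACLKA6_018112 at 10712 ± 2432 CPM (SD, n = 2), which lay at 12431 CPM in replicate 1 and 8992 CPM in replicate 2. It held 1.27% and 0.882% of the sense reads. The next, ACLKA6_009032, reached 10114 ± 391 CPM and was the highest gene of replicate 2, so the order of the 2 leading genes differed between pools. ACLKA6_000091 followed at 6819 ± 505 CPM, ACLKA6_010541 at 6495 ± 149 CPM and ACLKA6_001508 at 4934 ± 179 CPM. Of these 5 genes, ACLKA6_018112 varied most between the pools, by 1.38-fold, and ACLKA6_010541 least, by 1.03-fold. All 5 were read almost wholly on the sense strand, with at most 0.067% antisense reads in either library.

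Nearly all gene reads came from the annotated strand, though the reads had been used to predict the genes, so this share was not independent of the annotation. The sense share was 99.2% in replicate 1 and 99.0% in replicate 2, a mean of 99.1% ± 0.121 (SD, n = 2), from 46610675 and 39026623 sense reads. For the median gene the antisense share was lower still, at 0.227% and 0.231% over the 13773 models with at least 10 reads on both strands together in each library. An antisense share over 5% in each library was found in 1341 of these models (9.74%). Across genes, the antisense share of one library followed that of the other (Pearson r = 0.958 over 13773 genes, which are not independent replicates).

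A group of 326 models (2.37% of the 13773) had more antisense than sense reads in both libraries. These few models carried 51.8% of all antisense gene reads in replicate 1 and 53.7% in replicate 2. In 136 of them over 9 of 10 reads were antisense in each library, and 46 had no sense read at all in either. The group was mostly of low depth, with a median of 49 antisense reads in replicate 1, and 116 models had at least 100 reads in each library. The model with the most reads in the group, ACLKA6_005035, had 41864 antisense against 6 sense reads in replicate 1 and 38207 against 9 in replicate 2, an antisense share of 99.99% in replicate 1 (95% Wilson interval 99.97 to 99.99). ACLKA6_015732 had 24945 antisense and 533 sense reads in replicate 1 (97.9% antisense, 97.7 to 98.1), and 19991 and 533 in replicate 2 (97.4%, 97.2 to 97.6). Neither of these 2 models lost a read when counted without strand, so no annotated exon of the other strand shared those reads. Over the whole group, 79 models lost at least 10% of their reads without strand and 189 lost none.

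**Figure D2:**
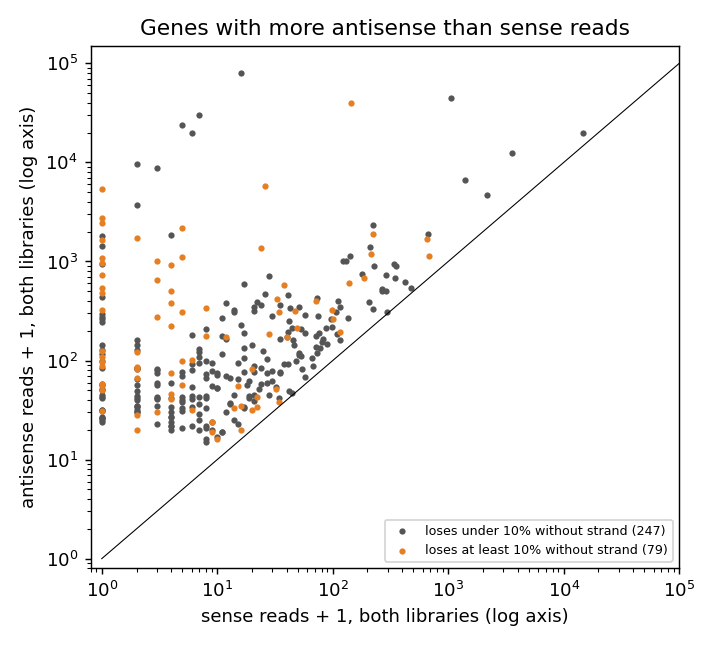
Antisense against sense reads, summed over the 2 libraries with 1 added and on log axes, for the 326 models with more antisense than sense reads in both. Each point is a model and the line marks equal numbers. The 79 models in orange lost at least 10% of their reads when counted without strand, and the other 247, in grey, lost less.

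Genes whose exons overlap on opposite strands lose reads when strand is ignored, because such reads cannot be given to either. This affected many genes slightly and few strongly. Of the 13454 models with at least 10 sense reads in each library, 4063 (30.2%) lost at least 1 read of their stranded sum in either library. Only 143 (1.06%) lost at least 10% of that sum, and 17 lost at least 50%. The sum includes antisense reads, so such a loss need not bring a model below its sense count. Among all models, 663 in replicate 1 and 651 in replicate 2 had fewer reads without strand than on the sense strand. Ambiguous reads numbered 298002 without strand and 238250 with sense counting in replicate 1, and 230226 and 170537 in replicate 2, a rise of 59752 and 59689 reads.

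The 2 pools gave closely similar profiles, with a minority of mostly low-expressed genes far apart. Across the 13454 models, log2(CPM + 1) correlated with Pearson r = 0.985 and Spearman rho = 0.982, values across genes, which are not independent replicates. The median absolute difference between the pools was 0.22 on the log2 scale, and 96.3% of models lay within 2-fold and 81.0% within 1.5-fold. The libraries were not duplicates of each other: a chi-square test of the 2 columns of counts gave 92.4 per degree of freedom over 13453 degrees, far above sampling noise. The common biological coefficient of variation between pools was 20.5% (edgeR). Each pool gave 1 library, so biological and technical parts of this spread cannot be told apart.

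Of 13702 genes tested, 583 (4.25%) differed between the libraries by at least 2-fold at an adjusted p under 0.05 (two-sided exact binomial test of the reads of the 2 libraries, Benjamini-Hochberg). Of these, 368 were higher in replicate 2 and 215 in replicate 1. They were mostly genes of low expression: 465 of 4425 tested genes under 10 CPM were called, against 15 of 1786 at 100 CPM or more. Together the called genes held 0.627% of the sense reads of replicate 1 and 1.54% of replicate 2, and without 4 consecutive tags, ACLKA6_004813 to ACLKA6_004816, chosen after their values were seen, the others held 0.520% and 0.682%. The median called gene differed by 1.34 on the log2 scale, and 101 differed by over 4-fold, 59 higher in replicate 2 and 42 higher in replicate 1. The test compares these 2 libraries and not conditions, and without the fold minimum 8135 genes (59.4%) passed the adjusted p.

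Among called genes with at least 100 reads in total, ACLKA6_019586 was the farthest apart, with 7 sense reads in replicate 1 and 445 in replicate 2 (log2 difference 6.20, exact 95% interval 5.25 to 7.62, exact binomial adjusted p = 7.65e-142). ACLKA6_004128 followed, with 11 and 340 reads (log2 difference 5.20, interval 4.40 to 6.28). In the other direction ACLKA6_016392 had 143 reads in replicate 1 and 6 in replicate 2 (log2 difference -4.15, interval -5.73 to -3.11), and ACLKA6_000320 had 192 and 11 (log2 difference -3.75, interval -4.84 to -2.94). The first 3 of these genes had no antisense read in either library. These intervals cover counting error within the libraries only.

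**Figure D3:**
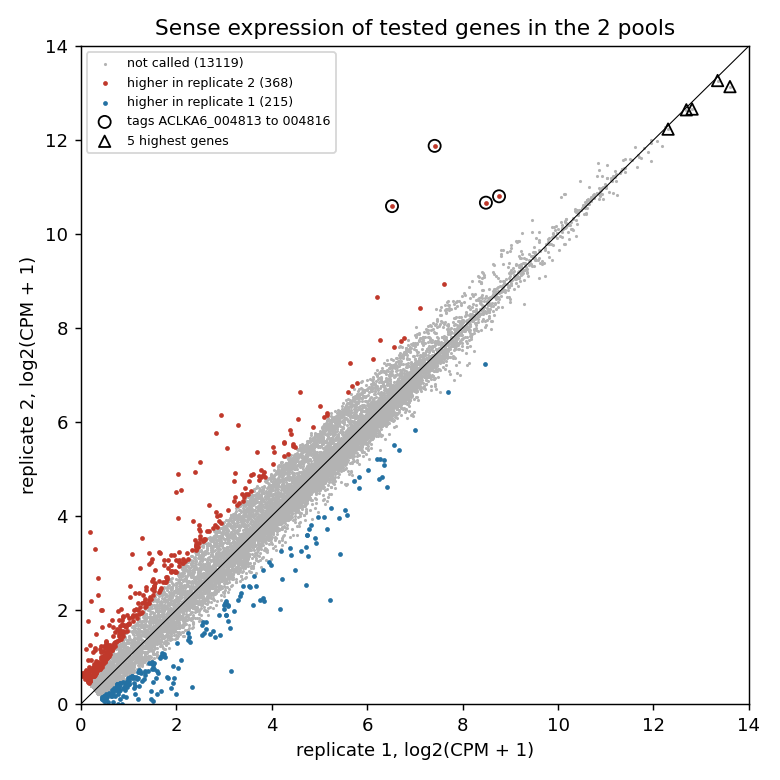
Expression of the 13702 tested genes in the 2 pools, as log2(CPM + 1) of sense reads in replicate 1 (x axis) and replicate 2 (y axis); the line marks equal expression. Red points (368) and blue points (215) are genes called higher in replicate 2 and in replicate 1, triangles are the 5 highest genes, and circles are 4 consecutive locus tags, chosen after their values were seen, that lie 4.11- to 22.1-fold above replicate 1.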

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

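The tests of strand marking and of overlapping genes over the 326 models below were fixed before their results were seen, and that of overlapping genes over the 46 models was chosen after; both items were chosen after the tables were examined. Reads assigned to no annotated feature, which no comparison of genes uses and which include any intronic reads, made up 21.7% of all reads on average, or 13139025 and 12643793 reads. In the antisense column, 46 models had no sense read in either library and at least 10 antisense reads in each, above the 3 that a count of 0 allows.

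The 46 are part of the 326 models with more antisense than sense reads in both libraries. Imperfect strand marking by the kit is argued against only for an even rate over genes. With the library-wide antisense share at every gene, the expected number of such models was 0 at 6 decimals, against 326 observed. At shares of 0.795% in replicate 1 and 0.966% in replicate 2, that expectation lies near 0 in any case. Strand marking that differs between genes was not tested. Reads of an annotated gene whose exons overlap on the other strand are argued against for the group as a whole, since 24.2% of the 326 models (95% Wilson interval 19.9 to 29.2) lost at least 10% of their reads without strand; for those 79 models this explanation stays open. Of the 46 models with no sense read, 18 (39.1%, 95% Wilson interval 26.4 to 53.5) lost as much, and for these it stays open too. The interval spans the bound of 50%, so the test decides nothing for the 46 as a set. Taken singly, the others of the 46 lost under 10%, which argues against this source for most of their reads. For all models that lost less than 10%, other explanations were not tested, since gene coordinates were not used here. These are a gene model placed on the wrong strand, an extension of a neighbouring transcript beyond its model and transcription from both strands. No biological explanation was tested, because the design names no contrast.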

How the results depend on the processing

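Of 98 alternative values, 32 could not leave the tolerance by construction (each library alone against the SD of the 2, unmapped and multimapping reads without strand, and the direction of the log2 ratios of 4 genes named for their large ratios) and say nothing about stability. The share in the 100 highest genes is not among the 32, because these genes were ranked anew in each library alone. Of the other 66, 53 stayed within the tolerance and 13 moved; the tolerance was 1.5 times for counts of genes, 1 SD between libraries for shares, 0.01 for the correlation and 10% for the coefficient of variation. The 1.5-fold minimum combined with total-read scaling was added after seeing the data. The 583 genes called between the libraries became 270 with a minimum of 50 reads, 2435 at 1.5-fold, 101 at 4-fold and 2298 at 1.5-fold with total-read scaling. The part of them higher in replicate 2 was 63.1%, against 56.5% with total-read scaling, 64.3% with DESeq2 size factors and 77.1% at 1.5-fold. The 326 antisense-majority models became 669 with a minimum of 1 read, 159 with a minimum of 50, 136 with antisense over 9 of 10 reads and 189 when models that lost reads without strand were left out. The 4063 models that lost reads without strand became 143 at a loss of at least 10%. The sense share was 98.9% in models with no such loss and 98.8% without the 100 highest genes, and the ambiguous share was 0.440% without strand. The correlation ranged from 0.984 to 0.993 and the coefficient of variation from 19.6% to 21.1% over their alternatives. The number of detected models lay between 12115 (minimum of 50 reads) and 15195 (minimum of 1 read). With each library alone, detected models ranged from 13618 to 13732, antisense-majority models from 416 to 427 and models losing reads from 2773 to 3061. The share in the 100 highest genes was 25.3% in replicate 2 alone and 25.8% in replicate 1 alone, and the latter moved out of the tolerance. Differences between libraries, their correlation and the coefficient of variation have no value with 1 library. No paired analysis was possible because the series has 1 group. Depth limits the ratios of genes under 1 CPM, but its part in their spread was not separated from other differences. The spread between libraries of the 1220 such genes that were tested was 0.97 (SD, log2), against 0.36 at 100 to 1000 CPM and 0.44 over 1000 CPM. The median absolute log2 ratio of these 3 classes was 0.547, 0.175 and 0.0764, so the larger SD over 1000 CPM was not a wider spread of the typical gene. That class held 2 called genes among 154.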

Other observations

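The called genes of highest expression were 4 consecutive locus tags, ACLKA6_004813 to ACLKA6_004816, chosen after their values were seen. Together they held 0.107% of the sense reads of replicate 1 and 0.854% of replicate 2. ACLKA6_004814 had 8063 reads in replicate 1 and 143787 in replicate 2, a 22.1-fold difference (log2 difference 4.47, exact 95% interval 4.43 to 4.50), and ranked 917 and 11 among all genes of the respective library. ACLKA6_004813 differed by 17.0-fold, and the other members by 4.11- and 4.53-fold. The longest run of called tags had 5 members, ACLKA6_008388 to ACLKA6_008392, all higher in replicate 2, by 2.02- to 6.99-fold, at under 30 CPM in either library.

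The tests of over 4-fold differences, of permutation within expression classes and of split transcripts were chosen after related results were seen; the others were fixed beforehand. An even spread between pools of 20.5% gave a median of 377 calls over 20 redraws (330 to 419), against 583 observed. This met the bound set beforehand for the number of calls, but no redraw reached the observed number. The 20.5% was also estimated from these same 2 libraries with called genes included, so a near total says little for it. An even spread is argued against for the shape of the differences: it gave at most 9 genes over 4-fold, against 101 observed. It also gave 154 to 210 calls at 10 CPM or more, against 118 observed. The total thus mixes too many calls there with too few at lower expression. A difference in the make-up of the pools, such as the ratio of the sexes or their physiological state, stays open and untested, since the labels give neither per pool.

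Called genes also sat beside each other in the numbering of the tags, in 41 runs of 2 to 5 tags that held 96 genes. Of 11818 pairs of consecutive tags that were both tested, 55 pairs were called in the same direction and 16 in opposite directions, against a mean of 11.4 same-direction pairs and a highest of 27 over 10000 random orders (permutation p = 1e-04, the smallest they can give). Crowding of the calls into low-expression classes is argued against, since orders permuted within class gave a mean of 11.5 and at most 26, and 52 pairs were left without the run ACLKA6_004813 to ACLKA6_004816. One transcript split over consecutive models stays open, and the test could hardly have argued against it. The median difference in log2 ratio between the members of the 55 pairs was 0.464. That is above the 0.137 to 0.292 that equal ratios give with counting noise alone, which is a lower bound on technical noise. It is within the 0.254 to 0.579 of random pairs of genes called in the same direction, whose median was 0.393, so the pairs were no more alike than random ones. By the rule only a value above that second range would argue against a split, and unrelated genes rarely reach it. This was the third form of that test; the first 2, a Fisher test per pair and a fixed bound of 0.1 for the median, had argued against a split in part or all of the runs and were dropped after their results were seen, the former because it allows for counting noise only and the latter because it ignores it. A candidate explanation is that clusters of neighbouring genes vary together between pools, but whether consecutive tags lie side by side in the genome was not tested.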
